A study of Homo sapiens with 12 samples.

How the data were processed

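Poly(A)-selected RNA of 12 MEC1 samples was made into stranded libraries and sequenced in 3 paired-end technical runs per library, per the labels' protocols. Cells were treated for 6 h with 75 nM H3B-8800 or DMSO before RNA extraction, and the groups were taken from the genotype and treatment in the labels. The submitters' processing notes name cutadapt 2.4 for adapter trimming and the genome build hg38. The aligner, the event tool and its version are not given in the sources used here; the layout of the table and its event names are those of a vast-tools inclusion table.

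The deposited table gave, per the file headers, the inclusion level of each splicing event in percent for each sample: the share of transcripts with an exon included, an intron retained or an alternative splice site used. It held 721551 events. Beside each percent value the authors deposited a text column with read coverage scores, the raw junction reads and the corrected numbers of inclusion and exclusion reads. Percent values were not normalized between samples, since each is a ratio within one sample. In 4598029 values with at least 10 reads, the deposited percent was compared with inclusion reads over inclusion plus exclusion reads, and 0 differed by more than 1 point. Read numbers were missing in 16884 cells. Another 36 columns held the single runs of the same samples, 3 per sample, and were not used. A corrected read number is not a number of molecules, since the libraries had no molecular identifiers, so the intervals given, and the limit of 3 reads that a level of 0% allows, cover counting error only.

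The choices of test, filter, gene lists and named genes were made before the data were examined, except where the text says otherwise. An event was tested when inclusion plus exclusion reads were 20 or more in every one of the 12 samples, which left 313032 events. A mean inclusion level between 1% and 99% left 127793. Introns whose exon-intron junctions were unbalanced (p under 0.05 in the deposited balance test in more than 6 samples) were left out, which left 120596. Site number 1 of each alternative 3' or 5' event was not tested, because the shares of an event's sites sum to 100%, which left 109076: 46277 exons, 45188 introns, 10469 alternative 3' sites and 7142 alternative 5' sites. The filter on reads in every sample favours highly expressed genes. A retained intron gives few unspliced reads when its transcript is degraded, so levels describe the transcripts present.

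Each event's logit, log2 of inclusion reads plus 0.5 over exclusion reads plus 0.5, was fitted with limma 3.58.1 in R 4.3.3 over all 12 samples as 4 groups, with the mean log2 read number as trend of the variance. The 4 groups shared one estimate of the spread because each has 3 samples. The contrasts were K700E against WT in DMSO, H3B-8800 against DMSO in each genotype, and the difference of the H3B-8800 effect, K700E minus WT. An event was called at a Benjamini-Hochberg adjusted p under 0.05 over all events of the contrast and a difference of group means of at least 10 points. The difference of the effect was tested on the logit scale and its size is given in points, so the 2 can rank events differently.

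Spliced reads per gene were summed from the raw exon-exon junction reads of a gene's annotated introns, each intron once, and expressed on a reads-per-million scale (RPM, of these reads) as log2 RPM with 0.5 reads added. They measure spliced transcripts at annotated introns and not total expression. A junction that skips an exon counts only where it is itself an annotated intron. Exon skipping can therefore lower a gene's sum without a loss of spliced transcripts. Genes with a mean of at least 50 reads were tested, 10182 in all, with limma and a mean trend, and called at an adjusted p under 0.05. Genes that share junction reads with near-identical copies were not set apart, so values of ribosomal protein genes, which have many pseudogenes, are uncertain in this respect.

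The 15 gene lists fixed before the data were examined were mutant SF3B1 targets, apoptosis regulators, spliceosome core, SR proteins with hnRNPs and splicing kinases, B cell receptor signalling, the NF-kappaB and Toll-like receptor pathway, DNA damage response and p53 pathway, cell cycle, ribosomal proteins, immediate early and stress genes, nonsense-mediated decay with RNA export, B cell markers, T and NK cell markers, myeloid markers, and fibroblast with epithelial markers. For events, the number of list genes with a call was compared with 10000 random gene lists of the same size matched in 5 classes of tested events per gene (two-sided permutation test, Benjamini-Hochberg over lists). For spliced reads, limma's camera was used with a preset correlation of 0.01, and no camera call held with an estimated correlation. The myeloid list had 1 gene with enough spliced reads and was not tested.

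The rule for named genes took called events with a gene symbol, 1 per gene, whose 3 samples of one group all lay above or all below the 3 of the other, in order of the difference. For K700E against WT it named the 12 alternative 3' sites, 4 exons, 3 introns and 2 alternative 5' sites with the largest differences and each called member of the target list. For H3B-8800 in each genotype it named 8 exons, 8 introns, 3 alternative 3' sites, 3 alternative 5' sites, 2 members of each other list, and the tested events of MCL1, BCL2L1, BCL2L11, BCL2 and SF3B1. For the difference of the effect it named up to 10 events, and for spliced reads the 6 higher and 6 lower genes with the largest change and 2 called members of each list. Annotation of exons, introns and untranslated regions came from GENCODE on the same build. GC content was not analysed here, since no genome sequence was given. Results for some named genes are not reported here.

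Lengths were compared with two-sided permutation tests of 100000 resamples, and means per sample with exact permutation tests of 3 against 3, whose smallest p is 0.1. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and the R package data.table, version 1.17.8, did the remaining steps.

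Both fits were tested on simulated data for K700E against WT. In 109076 simulated events with 200 changed ones, changes of 20, 40 and 60 points were recovered in 50.7%, 88.1% and 95.5% when the samples varied by their median spread, and in 3%, 44.8% and 92.4% when they varied by their mean extra-binomial spread, with 0 false calls in either. A change of 20 points was therefore often missed in these simulations. Their changes started only from levels away from both ends of the scale, so the shares do not apply to sites hardly used in WT. In 10182 simulated genes with 200 changed ones, changes of 1.5-fold, 2-fold and 4-fold were recovered in 82.1%, 100% and 100%, with 12 false calls. Every simulated gene had the same log2 SD of 0.159, a median of the real spread, and samples were drawn independently. Real genes differ in spread and same-numbered samples correlate. Recovery of genes with a wider spread can therefore be lower, and false calls can differ.

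Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 19.3 to 167 over genes), so no sample was counted as a copy of another. The K700E replicates are separate edited clones and the WT replicates 2 cultures and an edited clone, so p-values measure a mixed spread of clones and cultures. It was 19.3 to 49.2 in WT DMSO and 76.3 to 167 in K700E DMSO by the same chi-square, while the fits shared 1 estimate. K700E against WT therefore partly overlaps with editing and cloning, which these samples cannot fully tell apart from the mutation. The labels give the same clone or culture the same replicate number in both treatments, which pairs DMSO and H3B-8800 samples. As a check, deviations from the group mean in spliced reads correlated with r = 0.658 to 0.925 between same-numbered samples of the 2 treatments, and those of events with r = 0.015 to 0.07. Numbers do not pair WT with K700E. Fits with the clone or culture as a replicate block were alternatives.

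The other alternatives tried for events were minimum reads of 10 and 50, a test on percentage points, weights from read numbers, 0.1 reads added, size thresholds of 15 points and none, no filter on mean inclusion or on intron balance, all alternative sites, a rule without a test, only the 6 samples of a contrast, each sample left out in turn and the edited WT clone left out. For spliced reads they were median-of-ratios scaling, other filters and pseudocounts, a 2-fold threshold and each sample left out in turn. For the lists they were Fisher's exact test, camera with an estimated correlation and fry. Leaving out K700E clone 1, leaving out the edited WT clone from spliced reads, adding unspliced junction reads and measuring distance from the most used site were added after the data were seen. So were the replicate block in the list tests and leaving out samples in the list and length tests.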

Results

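RNA splicing was measured by poly(A) RNA sequencing in MEC1, an established human B cell line derived from chronic lymphocytic leukemia. SF3B1 is a core protein of the splicing machinery that helps to recognise the branch point upstream of 3' splice sites, and K700E is its most frequent mutation in chronic lymphocytic leukemia. The cells carried either wild-type (WT) SF3B1 or the edited K700E allele. They were treated for 6 h with 75 nM H3B-8800, a small molecule that binds the SF3B complex and modulates splicing, or with the vehicle DMSO. The 12 samples formed 4 groups of 3: WT in DMSO, WT in H3B-8800, K700E in DMSO and K700E in H3B-8800. The 3 K700E samples of a treatment came from separate edited clones, labelled with the K700E base change and a further base change. WT replicates 1 and 2 were separate cultures, and WT replicate 3 was an edited clone labelled WT that carried the further base change alone. Differences of K700E from WT can therefore also stem from editing and cloning. Each sample had 45840233 to 56676172 reads over annotated exon-exon junctions, and a tested splicing event had a median of 171 to 303 reads per sample. At the median depth, an inclusion level of 50% had a 95% binomial interval of ± 6.48 points. Inclusion levels are given in percent as mean ± SD of the group (n = 3), differences between them in percentage points, and coordinates are on hg38.

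The first comparison asked how splicing differed with the K700E mutation, and it set K700E against WT in DMSO. Alternative 3' splice sites changed more often than other event types. The site in MFSD9, which encodes a putative transporter, rose from 6.48% ± 6.26 to 85.6% ± 3.41 (adjusted p = 0.000498). A site of ANKHD1, an ankyrin repeat protein gene, rose from 6.72% ± 2.05 to 81.5% ± 3.09 (adjusted p = 3.38e-06). A site in ORAI2, which encodes a subunit of store-operated calcium channels, rose from 2.57% ± 1.30 to 74.8% ± 5.39 (adjusted p = 8.15e-06). In MTERF2, which encodes a mitochondrial transcription factor, the tested site went the other way, from 78.4% ± 2.90 to 9.55% ± 2.26 (adjusted p = 0.00118).

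Of 109076 tested events in 9510 genes, limma called 382 events in 275 genes, 250 with a higher and 132 with a lower inclusion level in K700E. A call needed a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 10 points. The calls comprised 194 alternative 3' sites used more and 81 used less, 21 exons included more and 29 less, 32 introns retained more and 21 less, and 3 alternative 5' sites used more and 1 less. The site of an event that gives the shortest exon was not tested, and the shares of an event's sites sum to 100%. With that site included 271 events were higher and 265 lower, among them 211 alternative 3' sites used more and 208 less, so the excess of sites used more rests on this choice. The median use of the 194 raised 3' sites lay between 0.85% and 1.09% in the WT DMSO samples and between 22.0% and 23.5% in the K700E DMSO samples. These 194 sites were picked for that difference, so the gap describes them and does not test them. With weights from the read numbers, 633 events were called, 364 higher and 269 lower. The 21 exons included more and 29 less became 95 and 128 with these weights, 58 and 62 in a test on percentage points and 10 and 5 in a fit on the 6 DMSO samples alone. The 32 introns retained more and 21 less became 64 and 34 without the filter on intron balance, and 49 and 38 with the weights, and the introns retained more 17 in the fit on 6 samples. The count of exons included less became 10 without WT DMSO replicate 2, 16 without WT DMSO replicate 3, 15 without K700E DMSO replicate 2 and 14 without K700E DMSO replicate 3. The 21 introns retained less became 13 without WT DMSO replicate 2. The 1 alternative 5' site used less became 0 without WT DMSO replicate 2 or 3 and 2 without K700E DMSO replicate 1.

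The MFSD9 site belongs to an exon form on chromosome 2, 102732322 to 102732426, that overlaps coding sequence but matches no annotated exon. The ANKHD1 site lies on chromosome 5, 140438494 to 140438617, at an annotated coding exon, and the ORAI2 site on chromosome 7, 102436202 to 102436333, in an untranslated region. The MTERF2 site lies on chromosome 12, 106985115 to 106985225, also in an untranslated region. A site of the golgin gene GCC2, of an exon form on chromosome 2, 108486499 to 108486648, rose from 1.15% ± 1.99 to 73.6% ± 4.71. The site in the antisense transcript VPS9D1-AS1 on chromosome 16, 89712674 to 89712818, rose from 4.03% ± 2.13 to 70.4% ± 1.71. DPH5, an enzyme gene of diphthamide synthesis, used a site on chromosome 1, 100992637 to 100992754, at 0.71% ± 0.65 in WT and 66.7% ± 2.58 in K700E. In MAP3K7, which encodes the kinase TAK1 upstream of NF-kappaB, the site on chromosome 6, 90560076 to 90560234, rose from 6.40% ± 1.79 to 70.7% ± 4.21. The exon forms with these sites in GCC2, DPH5 and MAP3K7 overlap coding sequence but match no annotated exon. PGBD1 rose from 28.3% ± 8.92 to 91.7% ± 1.47, TTI1 from 2.00% ± 1.04 to 62.7% ± 5.18, SH2D2A from 3.94% ± 2.17 to 62.4% ± 4.33 and SUN1 from 6.59% ± 1.12 to 61.4% ± 5.05. The adjusted p of these 8 sites from GCC2 to SUN1 was at most 0.00232, and all 3 K700E samples lay above all 3 WT samples at each of them.

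**Figure D1:**
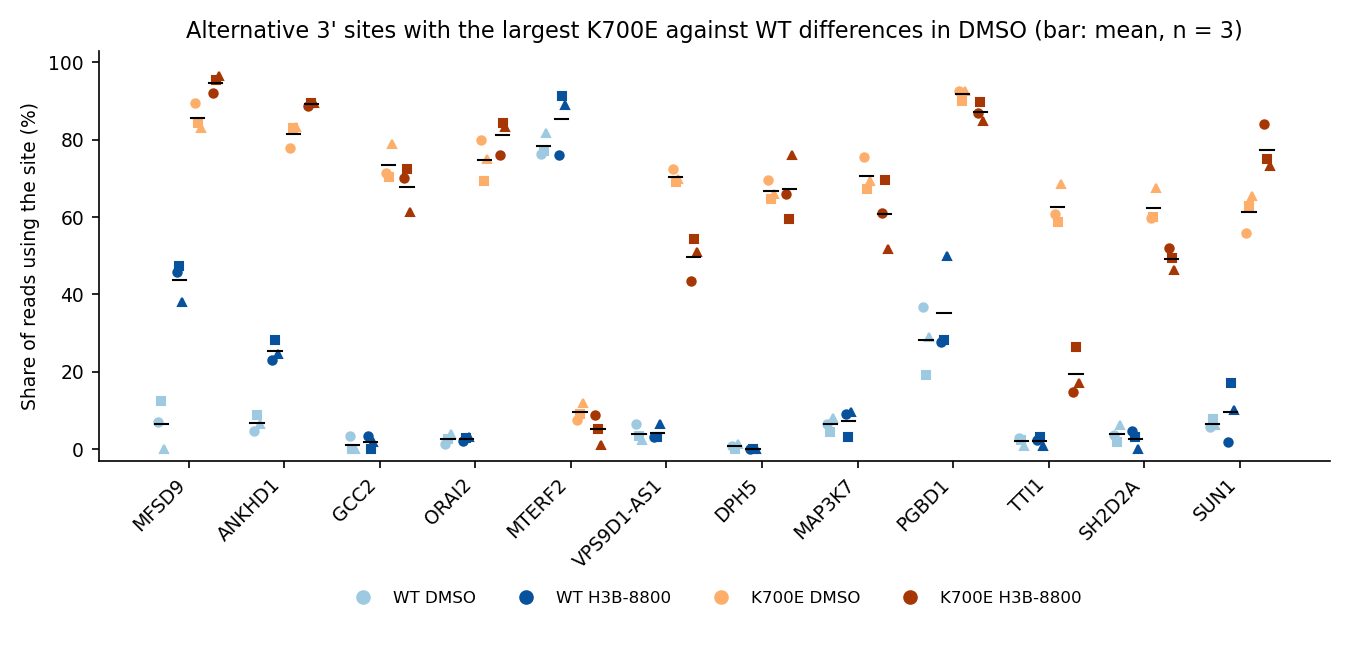
Share of reads using the site in percent (vertical axis) for the alternative 3' sites with the largest differences of K700E against WT in DMSO. Circles, squares and triangles stand for replicates 1, 2 and 3 of each of the 4 groups and bars for the group mean (n = 3). The MFSD9 site stood at 6.48% in WT and 85.6% in K700E in DMSO.

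Among exons, TTC3, a ubiquitin ligase gene, gained an exon (chromosome 21, 37197882 to 37198025, coding), which rose from 2.07% ± 2.44 to 56.6% ± 2.82 (adjusted p = 0.000118). BRD9, a subunit gene of the noncanonical BAF chromatin remodelling complex, gained an annotated coding exon (chromosome 5, 869245 to 869394), which rose from 6.16% ± 1.27 to 46.7% ± 4.54 (adjusted p = 4.06e-05). In NOL9 an exon inside an annotated intron (chromosome 1, 6546310 to 6546390) rose from 1.18% ± 0.76 to 39.2% ± 4.42 (adjusted p = 6.91e-05). The GGCX exon (chromosome 2, 85552485 to 85552567) rose from 33.3% ± 7.10 to 66.7% ± 3.61 (adjusted p = 0.0448), and this call was lost in 14 of 26 other settings. Among introns, retention in DCAF16, which encodes a substrate receptor of a ubiquitin ligase, fell from 39.6% ± 3.20 to 3.35% ± 0.64 (chromosome 4, 17804772 to 17805106, outside the coding part, adjusted p = 2.17e-05). The intron of RP11-242D8.1 (chromosome 17, 43167263 to 43170125) fell from 72.1% ± 9.41 to 17.1% ± 4.96 (adjusted p = 0.00186), and that of FKBP14 (chromosome 7, 30019124 to 30022664) from 79.0% ± 2.79 to 41.2% ± 10.6 (adjusted p = 0.0303, lost in 10 of 26 settings). The alternative 5' site of NAA16 rose from 34.8% ± 3.22 to 58.2% ± 3.31 (adjusted p = 0.0323, lost in 12 of 27 settings), and that of TPT1 from 80.6% ± 2.4 to 93.8% ± 2.01 (adjusted p = 0.0107, lost in 4 of 27 settings).

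Of the genes generally known for cryptic splicing with mutant SF3B1, a list fixed from general knowledge and not from these samples, 26 had a tested event and 17 had a call, against 0.93 expected from random gene lists matched on tested events (permutation over 10000 lists, adjusted p = 0.003, with a raw p of 2e-04 that is the smallest they can give). In 11 of the 17 an alternative 3' site was used more in K700E, and 9 genes had tested events without a call. Of the list's 335 tested events, 26 were called and 31 passed when adjusted over the list alone. Besides the genes above, TMEM14C rose from 1.39% ± 0.67 to 55.1% ± 7.35, ZDHHC16 from 1.59% ± 0.54 to 49.0% ± 2.43, SEPT6 from 2.4% ± 0.39 to 42.0% ± 2.33 and DYNLL1 from 3.97% ± 0.24 to 41.2% ± 2.05. SNRPN rose from 1.38% ± 0.32 to 16.9% ± 1.62. The TMEM214 exon rose from 2.79% ± 0.39 to 25.4% ± 2.74 and the ENOSF1 intron from 7.58% ± 2.62 to 30.5% ± 2.57, the latter not called in a fit on the 6 DMSO samples alone. The DLST exon fell from 89.1% ± 2.27 to 57.3% ± 5.70 and the SUGP1 intron from 17.6% ± 2.72 to 0.33% ± 0.29.

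No other list passed the permutation test against matched random lists (adjusted p = 1 for each). Calls were made in 2 of 32 apoptosis regulators, 2 of 46 SR proteins, hnRNPs and splicing kinases, 1 of 32 genes of B cell receptor signalling and 2 of 33 genes of the NF-kappaB and Toll-like receptor pathway. They were made in 1 of 44 DNA damage response and p53 genes, 1 of 46 cell cycle genes and 2 of 28 genes of nonsense-mediated decay and RNA export. The limma test called an event in 0 of 61 spliceosome core genes, 0 of 66 ribosomal protein genes, 0 of 27 immediate early and stress genes, 0 of 18 B cell markers, 0 of 3 T and NK cell markers and 0 of 2 fibroblast and epithelial markers. Over all events 14728 had an unadjusted p under 0.05. The myeloid list had 0 genes with a tested event in any comparison.

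Of the 194 raised 3' sites, 142 (73.2%) lay 10 to 30 nt upstream of the site that gives the shortest exon, against 2358 of 10194 uncalled sites (23.1%; two-sided permutation test over sites, p = 1e-05, the smallest that 100000 resamples can give). Sites are not independent replicates. The median distance of the 194 was 19 nt, with quartiles at 15 and 27.8 nt. Measured instead from the site most used in WT DMSO, a choice made after the data were seen, 170 of the 194 sites lay upstream, 75 of those 170 (44.1%) by a multiple of 3 nt. The means over all tested introns and exons of a sample did not separate the genotypes in DMSO. Mean intron retention was 4.16% ± 0.556 in WT and 4.4% ± 0.085 in K700E (exact permutation p = 0.9), and mean exon inclusion was 81.6% ± 0.037 and 81.6% ± 0.349 (exact permutation p = 1).

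The second comparison asked what H3B-8800 did to splicing in each genotype. In both, exons were skipped and introns retained in many genes. In WT, exon inclusion fell at the MOSPD2 exon from 96.5% ± 2.09 to 5.32% ± 1.64 (adjusted p = 1.31e-07) and at an exon of TRIM27, a ubiquitin ligase gene, from 98.0% ± 0.89 to 6.93% ± 0.91 (adjusted p = 6.56e-09). Retention of an intron of NEK8, a kinase gene of the primary cilium, rose from 4.07% ± 1.15 to 87.2% ± 7.59 (adjusted p = 3.19e-07). In K700E the same MOSPD2 exon went from 97.6% ± 1.91 to 8.77% ± 3.37 and the same NEK8 intron from 6.12% to 84.2% ± 3.62. An exon of MCL1, an anti-apoptotic BCL2 family gene on which many leukemia cells depend, fell from 96.9% ± 0.91 to 76.6% ± 5.58 in WT (adjusted p = 5.75e-06) and from 98.2% ± 0.77 to 72.6% ± 4.49 in K700E (adjusted p = 5.42e-07).

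In WT, limma called 34921 of the 109076 events (32.02%) in 7184 genes. They comprised 18642 exons included less and 231 more, 14412 introns retained more and 163 less, 647 alternative 3' sites used more and 320 less, and 381 alternative 5' sites used more and 125 less. In K700E it called 34148 events (31.3%) in 7157 genes. They comprised 17835 exons included less and 203 more, 14263 introns retained more and 165 less, 865 alternative 3' sites used more and 418 less, and 300 alternative 5' sites used more and 99 less. The exons included less had a median inclusion of 97.8% in DMSO and 68.9% in H3B-8800 in WT, and the introns retained more 3.37% and 26.6%, values of events picked for that direction. In K700E the medians of such events were 97.6% and 69.7% for exons and 3.63% and 25.8% for introns. Over all tested events of a sample, mean exon inclusion went from 81.6% ± 0.037 to 67.8% ± 0.392 in WT and from 81.6% ± 0.349 to 68.6% ± 0.447 in K700E. Mean intron retention went from 4.16% ± 0.556 to 14.5% ± 1.14 in WT and from 4.4% ± 0.085 to 14.3% ± 1.16 in K700E. The share of unspliced reads over annotated introns went from 2.21% ± 0.305 to 5.23% ± 0.643 in WT and from 2.35% ± 0.051 to 5.69% ± 0.52 in K700E. Each of these 6 differences separated all 3 samples from all 3 (exact permutation p = 0.1, the smallest that 3 against 3 allows).

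**Figure D2:**
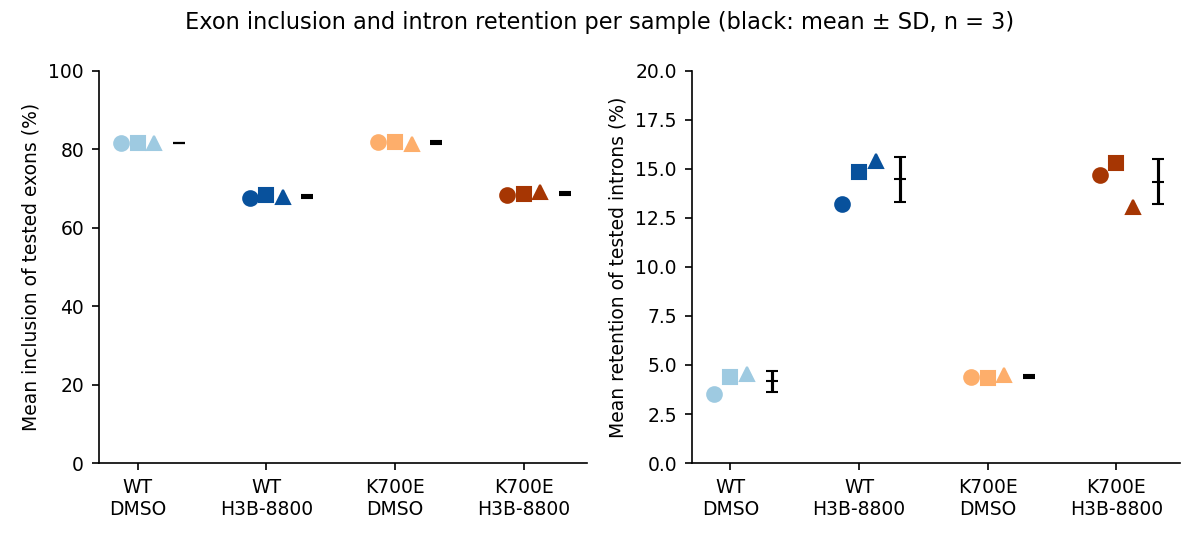
Mean exon inclusion and mean intron retention in percent (vertical axes) for each of the 12 samples, with circles, squares and triangles for replicates 1, 2 and 3 and a black bar with its error for the group mean ± SD (n = 3). Mean exon inclusion stood at 81.6% in both DMSO groups and at 67.8% and 68.6% in the H3B-8800 groups of WT and K700E.

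The TRIM27 exon (chromosome 6, 28907236 to 28907262) and the MOSPD2 exon (chromosome X, 14900575 to 14900635) are annotated coding exons, and the NEK8 intron (chromosome 17, 28734189 to 28734771) lies within the coding part. Other skipped exons in WT were those of IMPA1, from 94.8% ± 2.83 to 3.94% ± 0.45, RCBTB2, OSBPL7 and DUSP11, from 97.6% ± 0.41 to 8.40% ± 0.99. An exon of RAD54L, a homologous recombination gene, fell from 94.6% ± 1.00 to 5.43% ± 1.12. That of the deubiquitinase gene USP19 (chromosome 3, 49117437 to 49117570, coding) fell from 94.3% ± 2.60 to 5.20% ± 0.22. In K700E the USP19 exon went from 97.7% ± 1.02 to 8.02% ± 0.33, and an exon of SEPT7 from 94.6% ± 4.70 to 4.53% ± 1.63. The intron of the demethylase gene ALKBH3 (chromosome 11, 43882732 to 43883084, within the coding part) rose from 4.67% ± 1.52 to 87.1% ± 2.08 in WT and from 3.34% to 81.9% in K700E. The PCNT intron rose from 1.11% ± 0.65 to 83.0% ± 2.87 in WT, that of the Mediator gene MED12 from 7.21% ± 0.34 to 89.0% ± 3.09 and that of the kinesin gene KIF18B from 1.04% ± 0.31 to 79.5% ± 2.85. In K700E the MAST3 intron rose from 1.15% ± 0.47 to 88.7% ± 7.84.

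Alternative splice sites changed too. With the site that gives the shortest exon included, 762 alternative 3' sites were used more and 787 less in WT, and 992 and 1006 in K700E, and of the alternative 5' sites 450 and 450 in WT and 357 and 358 in K700E. The 3' site of DNAJC8 (chromosome 1, 28205258 to 28205349, coding) rose from 12.2% ± 4.32 to 93.6% ± 1.52 in WT and from 24.5% to 91.4% in K700E. That of DBF4, the regulatory subunit gene of the replication kinase CDC7, rose from 2.60% ± 1.09 to 80.2% ± 3.22 in WT and from 2.59% to 76.1% in K700E. The 5' site of the ribosomal protein gene RPS28 fell from 80.1% ± 5.25 to 11.9% ± 1.14 in WT and from 79.2% to 17.2% in K700E. Those of VIPAS39 and CDC16 rose in WT, the latter from 5.47% to 59.2%.

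**Figure D3:**
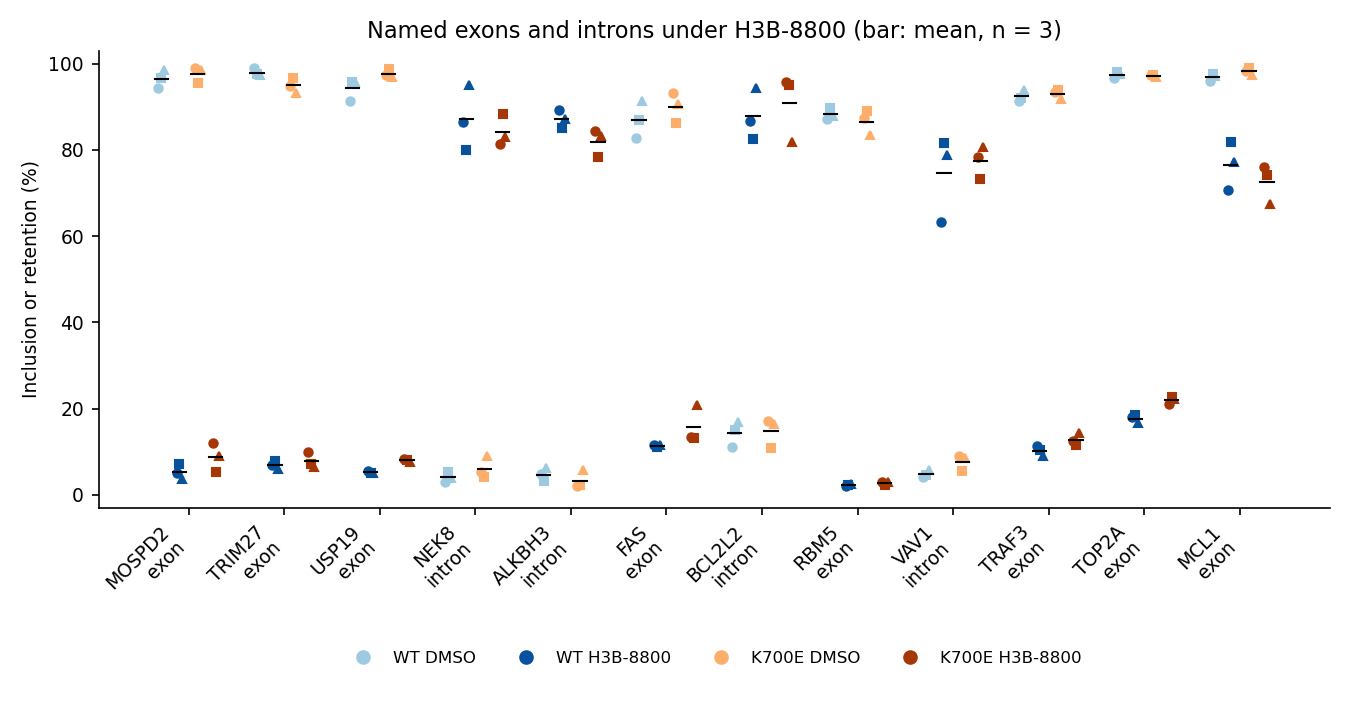
Inclusion or retention level in percent (vertical axes) of exons and introns called under H3B-8800, with circles, squares and triangles for replicates 1, 2 and 3 of the 4 groups and bars for the group mean (n = 3). The FAS exon stood at 87.0% in WT DMSO and 11.4% in WT H3B-8800, and the VAV1 intron at 4.83% and 74.6%.

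Among apoptosis regulators, 26 of 32 genes had a called event in WT and 25 of 32 in K700E, against 21.9 and 21.8 in matched random lists (permutation adjusted p = 0.435 and 0.519). The exon of the death receptor gene FAS that encodes its transmembrane part (chromosome 10, 89010753 to 89010815) fell from 87.0% ± 4.28 to 11.4% ± 0.23 in WT and from 90.0% ± 3.50 to 15.9% ± 4.38 in K700E. An intron of the anti-apoptotic gene BCL2L2 rose from 14.4% ± 2.99 to 87.8% ± 6.09 in WT. The MCL1 exon lies on chromosome 1, 150578244 to 150578491, in coding sequence. The intron next to it (150578492 to 150578842) rose from 8.52% ± 0.90 to 22.1% ± 4.15 in K700E (adjusted p = 0.000166), and stood at 11.4% ± 2.71 and 21.3% ± 1.58 in WT, where the difference of 9.98 points was under the size threshold (adjusted p = 0.00226). The BCL2L1 alternative 3' site (chromosome 20, 31722073 to 31722348, coding) rose from 39.4% ± 3.85 to 83.9% ± 4.61 in WT (adjusted p = 2.5e-05) and from 75.6% ± 2.05 to 96.6% ± 1.72 in K700E (adjusted p = 1.61e-05). BCL2L11, which encodes the pro-apoptotic protein BIM, lost an exon (chromosome 2, 111150044 to 111150147), which fell from 90.3% ± 1.30 to 44.1% ± 2.91 in WT. The BCL2 exon stood at 98.4% and 97.9% in WT (adjusted p = 0.69), and SF3B1 had no called event in either genotype.

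In the spliceosome core list 39 of 61 genes had a call in WT, fewer than the 48.4 of matched random lists (permutation adjusted p = 0.012), and 40 of 61 in K700E, against 48.3 (permutation adjusted p = 0.0465). Fisher's exact test without matching called neither (adjusted p = 0.126 and 0.3). The K700E value lost its call without K700E DMSO replicate 2 (0.051) or 3 (0.081) and without K700E H3B-8800 replicate 2 (0.1) or 3 (0.309). An exon of the splicing factor gene RBM5 fell from 88.3% ± 1.21 to 2.31% ± 0.25 in WT, and one of LUC7L from 96.9% to 25.6%. Ribosomal protein genes also had fewer called genes than random lists, with 18 of 66 against 33.95 in WT and 19 of 66 against 33.7 in K700E (permutation adjusted p = 0.003 for both). Random lists were not matched on event type. Of the 244 tested events of this list only 78 were introns and 15 exons, and the rest were alternative sites. Over all tested events, alternative sites were called less often than introns and exons. Within this list the 23 called events of WT held 1 intron and 2 exons, and the 23 of K700E held 1 intron and 3 exons. Of its 78 introns 1 was called higher in WT, against 31.9% of all tested introns. The mix of event types therefore does not account for the whole difference. RPL41 was among the called genes, at 73.3% in DMSO and 23.8% in H3B-8800 in WT. Immediate early and stress genes had 7 of 27 called against 14.3 in WT (permutation adjusted p = 0.017), a call lost without WT DMSO replicate 1 (0.084) or WT H3B-8800 replicate 3 (0.091), and 8 of 27 against 14.2 in K700E (permutation adjusted p = 0.062, but 5.64e-06 by Fisher's exact test). An exon of the chaperone gene HSPH1 fell from 98.1% to 52.7% in WT and an intron of DDIT3 rose from 47.5% to 84.8%.

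In the remaining lists the number of called genes did not pass the permutation test against matched random lists. Fisher's exact test called B cell receptor signalling in WT (adjusted p = 0.0393), the NF-kappaB pathway in WT and K700E (0.0393 and 0.00905) and DNA damage response in WT (0.00351). Among SR proteins, hnRNPs and splicing kinases 36 of 46 genes were called in WT and 32 of 46 in K700E (permutation adjusted p = 1 and 0.493), with the kinase gene SRPK2 at 91.3% and 10.4% and TIA1 at 81.1% and 8.67% in WT. In B cell receptor signalling 30 of 32 and 27 of 32 were called (0.865 and 1), and the intron of the signalling adaptor gene VAV1 rose from 4.83% ± 0.76 to 74.6% ± 9.79 in WT. In the NF-kappaB and Toll-like receptor pathway 31 of 33 and 32 of 33 were called (0.663 and 0.174), with the TRAF3 exon falling from 92.5% ± 1.33 to 10.3% ± 1.15 and that of the kinase gene IKBKB from 87.6% to 9.59% in WT. Among DNA damage response and p53 genes 42 of 44 and 40 of 44 were called (0.865 and 1), and a BRCA1 exon (chromosome 17, 43047643 to 43047703, coding) fell from 99.2% ± 0.39 to 21.9% ± 3.82 in WT and from 99.6% to 33.5% ± 1.36 in K700E. Among cell cycle genes 38 of 46 and 39 of 46 were called (1 and 1), with TOP2A, the gene of the mitotic topoisomerase, falling from 97.49% ± 0.66 to 17.7% ± 0.95 in WT. Nonsense-mediated decay and RNA export genes had 24 of 28 called in each genotype (1 and 1), among them SMG5, from 94.9% to 21.5% in WT. Among B cell markers 13 of 18 were called in each (0.865 and 1), among them the transcription factor genes IRF8, from 98.5% ± 0.64 to 28.3% ± 1.56, and EBF1, from 100% to 36.4% ± 5.43, in WT. T and NK cell markers had 3 of 3 and fibroblast and epithelial markers 1 of 2 in each, and mutant SF3B1 targets 20 of 26 and 18 of 26 (0.865 and 0.174). Counts of called events adjusted over the list alone were 105 in place of 106 for the mutant SF3B1 targets in WT, and 20 and 21 in place of 23 for ribosomal proteins in WT and K700E.

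Retained introns were shorter than others. In WT the 14412 introns retained more had a median length of 507 nt, against 1312 nt for uncalled introns, and in K700E the medians were 511 and 1309 nt. Skipped exons had medians of 102 nt against 112 nt in WT, and in K700E their median differed from that of uncalled exons by -12 nt. Each of the 4 differences had p = 1e-05 in a two-sided permutation test over events, the smallest that 100000 resamples can give, and events of one gene are not independent.

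The third comparison asked whether the effect of H3B-8800 differed between K700E and WT. The differences of H3B-8800 from DMSO in the 2 genotypes correlated across events with r = 0.963 for exons, 0.962 for introns, 0.847 for alternative 3' sites and 0.811 for alternative 5' sites, and with 0.972 over all types (slope 0.922). Of the called events 16345 exons were lower in both, against 7184.6 for independent lists of exons, and 12862 introns were higher in both, against 4549 for independent lists of introns. The DMSO samples of the 2 genotypes are different libraries, so no control is shared. The test of the difference called 9 events. Retention of an intron of LTN1, a ubiquitin ligase gene of ribosome quality control (chromosome 21, 28943905 to 28944382, within the coding part), rose from 2.07% ± 0.77 to 58.8% ± 4.72 in WT and from 3.20% ± 0.33 to 14.6% ± 3.92 in K700E, a difference of -45.3 points (adjusted p = 0.0343). The 3' sites of ACSF3, ATXN7, NPLOC4 and NOD1 had 0 reads in both WT groups, which allow levels of up to 0.58%, 1.17%, 0.12% and 2.63% in WT DMSO, and in K700E stood at 0.80%, 1.44%, 1.11% and 0% (up to 2.56%) in DMSO and at 18.1%, 17.9%, 13.9% and 12.2% in H3B-8800 (adjusted p = 0.0452, 0.0429, 0.0131 and 0.0326). The LNPK exon fell from 100% to 72.3% in WT and stood at 98.8% and 86.6% in K700E (difference 15.4 points, adjusted p = 0.0144).

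Another 3 events completed the set. The EDRF1 site stood at 97.8% and 98.9% in WT and at 94.9% and 71.9% in K700E (difference -24.0 points), the SOGA1 exon at 96.4% and 82.6% against 100% and 69.2% (difference -17.0 points), and the TAF2 exon at 0.22% and 8.75% against 18.95% and 15.1% (difference -12.4 points). Their adjusted p were 0.0429, 0.0401 and 0.0255. In all, 47 events had an adjusted p under 0.05 and 7890 an unadjusted one. No list had a called event for this difference (0 of the tested genes in each of the 14 lists with any). The count of 9 changed with single libraries left out: it became 0 without WT H3B-8800 replicate 3 or K700E H3B-8800 replicate 1 or 2, 2 without WT H3B-8800 replicate 2 and 3 without K700E H3B-8800 replicate 3. It became 5 without WT H3B-8800 replicate 1, 15 without K700E DMSO replicate 2 and 17 without WT DMSO replicate 1. With the clone or culture as a replicate block it was 0, with weights from the read numbers 1, with 0.1 reads added 39 and in a test on percentage points 728 (425 higher and 303 lower). Each of the 9 calls was lost in 7 to 16 of 24 or 25 other settings.

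**Figure D4:**
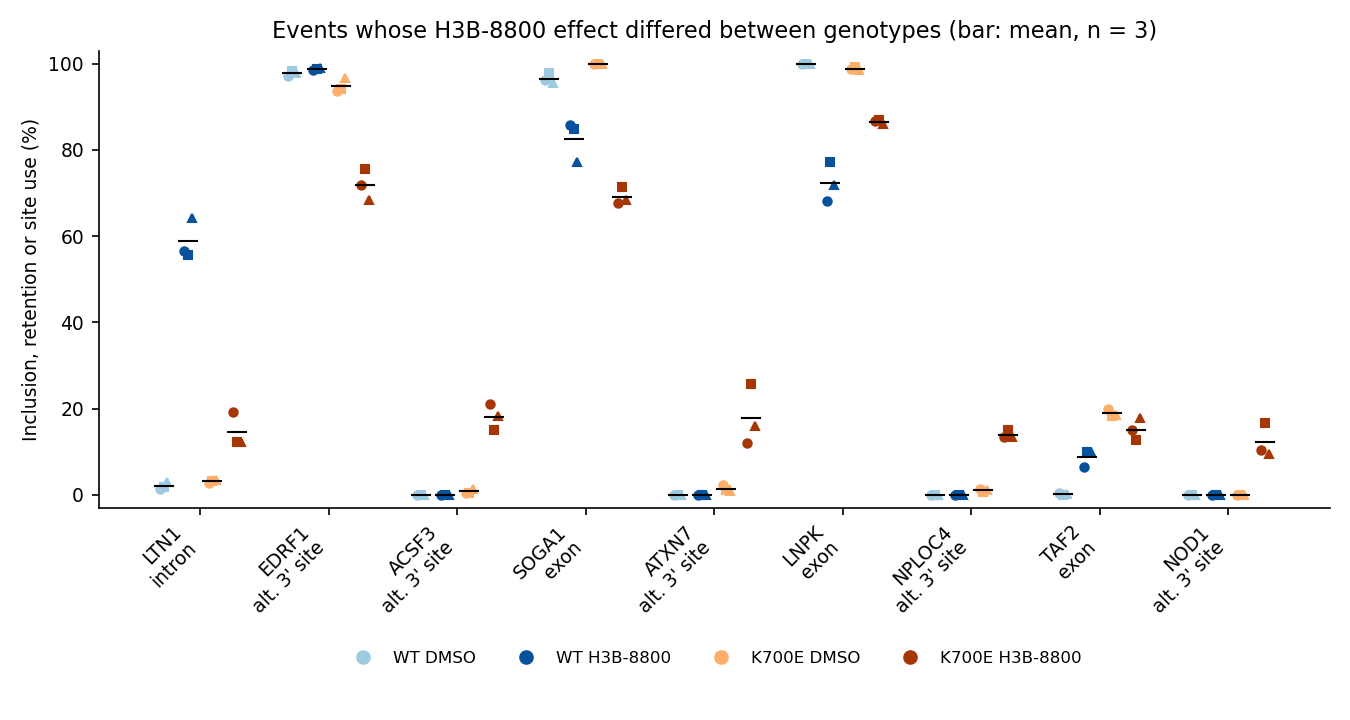
Inclusion or retention level in percent (vertical axes) of events with a called difference of the H3B-8800 effect between genotypes, with circles, squares and triangles for replicates 1, 2 and 3 of the 4 groups and bars for the group mean (n = 3). The LTN1 intron reached 58.8% in WT and 14.6% in K700E under H3B-8800.

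Spliced reads per gene were compared as a measure of spliced transcripts. They are the sum of reads over a gene's annotated exon-exon junctions on a reads-per-million scale (RPM), so exon skipping can lower them. The log2 fold changes below are ± SE from limma, on the scale of log2 RPM with 0.5 reads added. K700E differed from WT in DMSO in 495 of 10182 genes, 296 higher and 199 lower. The fit took its spread from all 12 samples as independent, although same-numbered samples of the 2 treatments correlated with r = 0.658 to 0.925. These p-values may therefore be too small, and no fit on the 6 DMSO samples alone was made for spliced reads. PPP2R5A, a regulatory subunit gene of a protein phosphatase, fell by 1.21 ± 0.15 on the log2 scale (75.9 ± 2.26 to 33.1 ± 5.7 RPM, adjusted p = 0.00226). MAP3K7 fell by 0.95 ± 0.12 (94.3 to 49.2 RPM, adjusted p = 0.00275). CDK6, a cell cycle kinase gene, rose by 0.98 ± 0.09 (22.5 to 44.5 RPM, adjusted p = 0.000401). Among the called genes the largest rises were those of ZEB2 (5.07 ± 1.10, from 0.163 ± 0.104 to 8.2 ± 9.7 RPM, adjusted p = 0.028) and FCRL3 (4.65), and the largest falls those of PRR34-AS1 (-6.09) and ACTN1 (-4.32). The SD of ZEB2 in K700E exceeded its mean, with K700E replicate 1 at 19.3 RPM and the other 2 clones at 1.69 and 3.57.

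Mutant SF3B1 targets were lower in K700E relative to other genes by camera (26 genes, 2 higher and 6 lower, 10 adjusted over the list alone, adjusted p = 0.000427, but adjusted p = 0.222 with an estimated correlation). Ribosomal protein genes were also lower (76 genes, 0 higher and 8 lower, 23 adjusted over the list alone, median -0.21, adjusted p = 3.39e-18, but adjusted p = 0.508 with an estimated correlation), RPL14 among them (-0.58). SR proteins, hnRNPs and splicing kinases were lower (47 genes, 1 higher and 2 lower, 4 adjusted over the list alone, adjusted p = 0.000427, but adjusted p = 0.222 with an estimated correlation), with HNRNPLL at 2.35 and SRSF7 at -0.38. The spliceosome core was lower (62 genes, 0 higher and 3 lower, 4 adjusted over the list alone, adjusted p = 0.0191, but adjusted p = 0.565 with an estimated correlation). Apoptosis regulators were higher relative to other genes (33 genes, 0 called by limma where 2287 of all genes had an unadjusted p under 0.05, 4 adjusted over the list alone, adjusted p = 0.0317, but adjusted p = 0.565 with an estimated correlation). DNA damage response and p53 genes were higher (46 genes, 4 higher and 0 lower, 4 adjusted over the list alone, adjusted p = 0.0318, but adjusted p = 0.648 with an estimated correlation), with the p53 target CDKN1A at 6.0 and 17.6 RPM. Without WT DMSO replicate 2 the adjusted p became 0.0628 for apoptosis regulators, 0.0527 for the spliceosome core and 0.0527 for DNA damage response genes. Without K700E DMSO replicate 1 it became 0.0633, 0.156 and 0.198, and without K700E DMSO replicate 3 it became 0.0759 for apoptosis regulators.

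The other lists did not differ from the remaining genes by camera. Of 32 B cell receptor signalling genes 3 were higher and 1 lower (5 adjusted over the list alone, adjusted p = 0.941), of 32 NF-kappaB and Toll-like receptor genes 1 and 1 (2, 0.153), of 46 cell cycle genes 2 and 0 (2, 0.406), of 32 immediate early and stress genes 3 and 0 (6, 0.941) and of 27 nonsense-mediated decay and RNA export genes 1 and 0 (1, 0.413). Of 19 B cell markers 2 were higher and 2 lower (5, 0.244), with the low-affinity IgE receptor gene FCER2 falling by 2.03 ± 0.34, from 386 ± 97.9 to 98.1 ± 37 RPM (adjusted p = 0.0102), and the class II antigen gene HLA-DPA1 rising by 1.10, from 482 to 1037 RPM. T and NK cell markers had 4 genes and 0 calls (0.803). Fibroblast and epithelial markers had 7 genes, 1 of them higher (2 adjusted over the list alone, 0.157): VIM, an intermediate filament gene that lymphoid cells also express, rose by 1.98 ± 0.35, from 44.0 ± 10.7 to 182 ± 79 RPM (adjusted p = 0.013). The summed level of that list was 44.4 to 87.3 RPM in the WT samples and 114 to 298 in the K700E samples. The median log2 fold change of cell cycle genes and of immediate early and stress genes turned from higher to lower with median-of-ratios scaling.

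These K700E counts moved when single libraries were left out. Without WT DMSO replicate 2 there were 55 higher and 49 lower genes, without WT DMSO replicate 1 79 and 66, and without WT DMSO replicate 3 112 and 59. Without K700E DMSO replicate 1 there were 125 and 125, and without K700E DMSO replicate 3 163 and 93. Without WT H3B-8800 replicate 2 or 3 the numbers were 179 and 137 or 197 and 144, and without the edited WT clone in both treatments 90 and 49. With median-of-ratios scaling 232 were higher and 280 lower, so that 45.3% in place of 59.8% of the calls were higher. Of the genes named, ZEB2, FCRL3, PRR34-AS1, ACTN1 and RPL14 lost their call without any 1 of the 3 WT DMSO replicates or without K700E DMSO replicate 1. CDKN1A and VIM lost it without WT DMSO replicate 1 or 2, HNRNPLL without WT DMSO replicate 2 or 3, SRSF7 without WT DMSO replicate 2, and FCER2 without the edited WT clone. In a principal component analysis K700E clone 1 stood apart on the second component (-50.8 and -62.5, with the other samples between -6.8 and 24.8), and without that clone 351 genes were higher and 313 lower.

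H3B-8800 changed the spliced reads of 6042 genes in WT, 1888 higher and 4154 lower, and of 5294 in K700E, 1653 higher and 3641 lower. Exon skipping under H3B-8800 can lower these sums, so genes with few skipped exons can rise relative to others. How much of the changes came from skipping was not tested. OVGP1 rose by 5.10 ± 0.26 in WT, from 1.15 to 39.5 RPM, and by 4.34 in K700E, from 1.64 to 32.4. DCHS1, a protocadherin gene, rose by 5.26 in WT and 5.16 in K700E. KCTD13 fell by 4.57 in WT, from 8.01 to 0.331 RPM, and TRMT61B by 4.50, from 16.3 to 0.742. The receptor gene CD40 fell by 2.52 in WT, from 64.8 to 11.4 RPM, and by 1.77 in K700E, and the replication gene CDC45 by 2.41, from 151 to 28.4, and by 1.83. The median log2 fold change of all genes was -0.28 in WT and -0.22 in K700E, and median-of-ratios scaling shifted it by 0.27 and 0.22. With that scaling 2978 genes were higher and 2984 lower in WT (49.9% in place of 31.2% of the calls higher) and 2691 and 2670 in K700E (50.2% in place of 31.2%). With the clone or culture as a replicate block 2841 genes were higher and 5550 lower in WT (33.9% of the calls higher), and 2734 and 5241 in K700E (34.3%). The main fit did not use this pairing, so its counts of genes changed by H3B-8800 can be too low.

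Ribosomal protein genes rose relative to other genes under H3B-8800, with 72 of 76 higher and 0 lower in WT (75 adjusted over the list alone, median 0.46, camera adjusted p = 4.75e-20) and 70 of 76 higher and 0 lower in K700E (73, median 0.41, adjusted p = 5.89e-20), but adjusted p = 0.44 and 0.452 with an estimated correlation. SR proteins, hnRNPs and splicing kinases were higher (25 of 47 higher and 11 lower in WT, 36 adjusted over the list alone, adjusted p = 8.38e-05; 24 and 10 in K700E, 35, adjusted p = 2.14e-05), but adjusted p = 0.275 and 0.205 with an estimated correlation. In this list SRRM1 rose by 1.38 in WT, from 290 to 755 RPM, RBM39 by 1.29 in K700E, from 394 to 962, and HNRNPU fell by 1.42 in WT, from 1454 to 543. The spliceosome core was higher (32 of 62 higher and 18 lower in WT, 50 adjusted over the list alone, adjusted p = 0.000414; 27 and 15 in K700E, 46, adjusted p = 0.000886), but adjusted p = 0.44 and 0.452 with an estimated correlation, with PRPF3 rising by 1.17 and U2SURP falling by 1.33 in WT. The medians of these 3 lists lay above 0 with either scaling. Median-of-ratios scaling raised all genes of a genotype alike, so this outcome was fixed in advance.

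Mutant SF3B1 targets were lower in WT (2 of 26 higher and 19 lower, 22 adjusted over the list alone, camera adjusted p = 0.0213), but adjusted p = 0.44 with an estimated correlation and 0.0686 with the clone or culture as a replicate block. In K700E 2 were higher and 12 lower (14, adjusted p = 0.336), and DVL2, a WNT signalling gene, fell by 2.32 in WT and by 1.86 in K700E. No other list passed by camera in either genotype. Apoptosis regulators had 9 higher and 6 lower of 33 in each genotype (15 and 15 adjusted over the list alone, adjusted p = 0.0981 and 0.0949), with BCL2L2 falling by 2.19 in WT and FAS rising by 1.21 in K700E. B cell receptor signalling had 6 higher and 14 lower of 32 in WT (21, 0.985) and 4 and 11 in K700E (15, 0.887), with VAV1 falling by 1.41 in WT. The NF-kappaB and Toll-like receptor pathway had 11 and 12 of 32 (23, 0.599) and 8 and 11 (19, 0.627). DNA damage response and p53 genes had 9 and 21 of 46 (31, 0.601) and 8 and 20 (28, 0.729), with the repair gene XRCC1 falling by 1.90 in WT, from 96.0 to 25.9 RPM. Cell cycle genes had 16 and 22 of 46 (38, 0.798) and 14 and 21 (36, 0.747).

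Immediate early and stress genes had 6 higher and 6 lower of 32 in WT (12, 0.127) and 5 and 3 in K700E (6, 0.0949), with the chaperone gene HSPA8 falling by 1.27 in WT. Nonsense-mediated decay and RNA export genes had 8 and 11 of 27 (19, 0.798) and 8 and 9 (17, 0.747), with THOC6 falling by 2.41 in WT. B cell markers had 1 and 5 of 19 (6, 0.898) and 0 and 4 (4, 0.887), with SPIB falling by 1.51 and CD79B by 1.18 in WT. T and NK cell markers had 0 and 2 of 4 in WT (2, 0.985) and no call in K700E (0.887), and fibroblast and epithelial markers 1 and 0 of 7 in WT (0, 0.524) and no call in K700E (0.729), where 5904 of all genes had an unadjusted p under 0.05 by limma. The median of the NF-kappaB, cell cycle, nonsense-mediated decay, B cell marker and T and NK cell marker lists lay below 0 in both genotypes and at or above 0 with median-of-ratios scaling, as did that of the fibroblast and epithelial markers in K700E. Camera, which compares a list with the other genes, put these lists on the higher side.

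The H3B-8800 effect on spliced reads differed between genotypes in 5 genes by limma, with 509 at an unadjusted p under 0.05. DCAF16 went from 3.03 to 0.664 RPM in WT and from 11.2 to 10.7 in K700E (difference of the log2 fold changes 2.14 ± 0.29, adjusted p = 0.0341). An intron of DCAF16 and a 3' site of SUN1, another of these genes, differed between the genotypes in DMSO. Such events can alter reads over annotated junctions, and their part in the differences given here was not tested. WDR6 went from 72.2 to 27.2 RPM in WT and from 86.6 to 67.3 in K700E (1.04), SUN1 from 219 to 268 and from 102 to 237 (0.93), CPSF4 from 73.8 to 17.8 and from 72.5 to 32.2 (0.88), and ELP2 from 138.6 to 83.5 and from 67.2 to 71.8 (0.82). Mutant SF3B1 targets lay higher in this difference (median 0.27, 0 called over all genes and 5 adjusted over the list alone, camera adjusted p = 3.62e-05), but adjusted p = 0.126 with an estimated correlation. Ribosomal protein genes lay lower (median -0.05, adjusted p = 0.000971), but adjusted p = 0.93 with an estimated correlation. Their call was lost without WT DMSO replicate 3 (0.596), WT H3B-8800 replicate 1 (0.646), K700E DMSO replicate 2 (0.405) or 3 (0.799) and K700E H3B-8800 replicate 1 (0.936). The count of 5 genes became 0 without any 1 of the 3 WT DMSO replicates, any 1 of the 3 K700E DMSO replicates, or WT H3B-8800 replicate 1 or 3. It was 1 without WT H3B-8800 replicate 2, 2 without K700E H3B-8800 replicate 3, and 0 without the edited WT clone or K700E clone 1 in both treatments. With the clone or culture as a replicate block it was 616, of which 485 lay higher and 131 lower in K700E. The main fit did not use this pairing, although same-numbered samples of the 2 treatments correlated with r = 0.658 to 0.925. Its count of 5 genes can therefore be too low.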

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

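The 8 counts over other splits of the samples and all other tests of this part were set out before their results were seen, except those of scaling and of low read numbers for the second pattern, which were chosen after. The bounds for reading 2 of them, the matched-site and the neighbour test, were tightened after first values were seen, so that a bound counts as passed only by more than its spread. Both are treated here as open.

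The H3B-8800 effect differed between genotypes, by the test of the difference itself, in 9 events, 5 genes and 2 lists. The differences, K700E minus WT in points, were -45.3 for the LTN1 intron, -24.0 for the EDRF1 site, 17.3 for the ACSF3 site, -17.0 for the SOGA1 exon, 16.4 for the ATXN7 site, 15.4 for the LNPK exon, 12.8 for the NPLOC4 site, -12.4 for the TAF2 exon and 12.2 for the NOD1 site. In spliced reads the differences of the log2 fold change were 2.14 for DCAF16, 1.04 for WDR6, 0.93 for SUN1, 0.88 for CPSF4 and 0.82 for ELP2. The list medians were 0.27 for mutant SF3B1 targets and -0.049 for ribosomal proteins, but camera with an estimated correlation called neither list (adjusted p = 0.126 and 0.93), and fry gave 0.0125 and 0.851. With the clone or culture as a replicate block, 0 events and 616 genes were called, and a test on percentage points called 728 events. The main fit did not use the pairing of the treatments, so its count of genes can be too low. The events became 0 without WT H3B-8800 replicate 3 or K700E H3B-8800 replicate 1 or 2. The genes became 0 without any 1 of the 3 WT DMSO or the 3 K700E DMSO replicates, or without WT H3B-8800 replicate 1 or 3. Leaving out any other single library gave 2 to 17 events and 1 to 5 genes.

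The first pattern is that the 194 alternative 3' sites raised in K700E were also used more in WT under H3B-8800, by a median of 0.466 points, with 21 called higher and 3 lower in WT. Choosing sites for low values in the WT DMSO samples they were then compared with was argued against: with each WT DMSO replicate held out of the choice, the median rises over the held-out replicate were 0.417, 0.406 and 0.532 points, each with an interval above 0. It stays open whether all little-used sites rise alike. Matched uncalled sites rose more (median 1.386, 95% of random sets between 0.921 and 1.935), a result that neither stated bound had foreseen. The filter on a mean inclusion of at least 1% over the 12 samples favours such a rise. The raised sites could pass through their use in K700E, but an uncalled site under 1% in WT DMSO had to be higher in other groups. The test can therefore not decide this question. A response of K700E-sensitive sites in particular is therefore not shown by these data.

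The second pattern is 15 genes with at least 4-fold more spliced reads under H3B-8800 in both genotypes, among them DCHS1, OVGP1, CMYA5, GZF1 and RASL11A. Scaling to total spliced reads shifts all genes alike. The median log2 fold change of all 10182 genes was -0.28 in WT and -0.221 in K700E (upper ends of the bootstrap intervals -0.259 and -0.207). Values scaled to the total could hardly have given a 4-fold median, so this test decides nothing. With median-of-ratios scaling all 15 genes stayed called and at least 2-fold higher in both genotypes. That scaling raised all log2 fold changes of a genotype by the same amount, so this could hardly have come out otherwise. Counting noise from a handful of reads in DMSO was argued against by choosing such genes without 1 replicate number at a time: in the replicate held out, the median log2 ratio of H3B-8800 to DMSO over the 16 or 17 genes chosen was 2.61 to 3.26, with DMSO reads under 3 taken as 3. The lowest end of the 6 bootstrap intervals was 2.28. It stays open whether transcripts may run on from an upstream gene on the same strand: 26.7% of the genes had such an expressed neighbour within 10 kb (exact binomial interval 7.8% to 55.1%), against a median of 13.3% in random sets, of which 95% lay between 0% and 33.3%. An effect of the compound on these genes themselves was not tested.

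The third pattern is that 165 genes with an upstream 3' site raised in K700E had fewer spliced reads in K700E, with a median log2 fold change of -0.081 against 0.058 in matched random sets (95% between 0.015 and 0.101). Reads leaving the annotated junction were argued against as the whole cause, since without the introns at the changed site the median was -0.061 (bootstrap interval -0.14 to 0.009, against 0.013 as the lower bound of random sets). A difference of K700E clone 1 was argued against, since the median without it was -0.15. As a hypothesis, transcripts shifted out of frame may be lost. Frame was set only by the distance between sites, whether or not a site lay in coding sequence. By this distance 90 genes had an out-of-frame site and 72 an in-frame site. The median of the former lay 0.21 below that of the latter (difference -0.21, two-sided permutation p = 0.0043 over genes). The test could have come out either way. Some raised sites, such as that of ORAI2, lie in an untranslated region. The split is therefore not one of coding frame shifts alone. Decay itself was not measured, and other causes tied to the genotype stay open.

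For each comparison the 6 or 12 samples make only 10 splits of the kind counted, too few for a share under 0.05, and 1 split, the real one, gave as many calls in each. For events the real value and the highest of the other splits were 382 and 3 for K700E against WT, 34921 and 0 for H3B-8800 in WT, 34148 and 0 in K700E and 9 and 1 for the difference of the effect. For spliced reads they were 495 and 0, 6042 and 0, 5294 and 0, and 5 and 0. In the other splits any real difference lies inside the relabelled groups and widens their spread. Few calls there were therefore favoured by construction, and these counts do not test chance.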

How the results depend on the processing

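Leaving out K700E clone 1 in both treatments, leaving out the edited WT clone from spliced reads, adding unspliced junction reads, and the replicate block in the list tests were chosen after the data were seen. So were the distance from the most used site and the single samples left out in list and length tests. Over the alternatives that leave out no single sample, 301 values of counts, lists and lengths stayed on their side of the threshold or within 1.5 times, 38 counts moved further, 22 calls were lost, 11 were gained and 3 list results turned direction. For the single events and genes named, 2958 such values kept their call and 144 lost it, and none reversed. The cause of a change was not tested, except that a size threshold changes counts by its construction and leaving out samples lowers their number. In simulated data a change of 20 points was recovered in 50.7% with the median spread of the samples. With their mean extra-binomial spread it was recovered in 3%. These changes started only from levels away from both ends of the inclusion scale.

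Counts of events moved as follows. With no size threshold, K700E against WT had 2217 calls (686 alternative 3' sites higher), H3B-8800 in WT 79048 (35822 exons lower and 34882 introns higher), H3B-8800 in K700E 78006 (35348 and 34488) and the difference of the effect 47. With weights from read numbers K700E against WT had 633 and the difference of the effect 1. The latter, 9 as reported, was 728 on percentage points, 39 with 0.1 reads added, 15 with no filter on mean inclusion, 14 with all alternative sites, 1 without the edited WT clone and 1 without K700E clone 1.

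Counts of genes in spliced reads moved as follows. With median-of-ratios scaling 2978 were higher in WT and 2691 in K700E under H3B-8800. With the 2-fold threshold K700E against WT had 99 higher and 47 lower, H3B-8800 303 and 1931 in WT and 169 and 1411 in K700E, and the difference of the effect 2. Without the edited WT clone K700E against WT had 90 higher and 49 lower and the difference of the effect 0. Without K700E clone 1 the former had 313 lower and the latter 0, and with unspliced reads added the latter had 3.

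With the clone or culture as a replicate block, the difference of the effect had 0 called events and 616 called genes, H3B-8800 raised 2841 and lowered 5550 genes in WT and raised 2734 and lowered 5241 in K700E, and the target list in WT had an adjusted p of 0.0686. For K700E against WT the numbers do not pair samples, and a replicate block on the number gave 631 higher and 390 lower genes. There, same-numbered samples had r = -0.149, 0.224 and 0.117 in spliced reads, so not every sample went best with its own number.

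For genes with a called event, Fisher's exact test without matching gave an adjusted p of 0.126 in WT and 0.3 in K700E for the spliceosome core, 0.0393 in WT for B cell receptor signalling, 0.0393 in WT and 0.00905 in K700E for the NF-kappaB pathway, 0.00351 in WT for DNA damage response and 5.64e-06 in K700E for immediate early and stress genes. For spliced reads, camera with an estimated correlation gave in K700E against WT 0.222 for targets, 0.222 for SR proteins and hnRNPs, 0.565 for apoptosis regulators, 0.565 for the spliceosome core, 0.648 for DNA damage response and 0.508 for ribosomal proteins. Under H3B-8800 it gave 0.44 in WT for targets, the spliceosome core and ribosomal proteins, 0.452 in K700E for the latter pair, and 0.275 and 0.205 for SR proteins and hnRNPs. For the difference of the effect it gave 0.126 for targets and 0.93 for ribosomal proteins.

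The test fry asks whether a list's genes move one way on balance, not whether they differ from other genes. In K700E against WT it gave 0.372 for the spliceosome core, 0.0828 for DNA damage response, 0.0821 for ribosomal proteins, and 0.0186 for cell cycle genes and for fibroblast and epithelial markers. Under H3B-8800 it gave 0.0292 for B cell receptor signalling and 0.00148 for DNA damage response in WT, and 5.33e-05 for targets and 0.00776 for DNA damage response in K700E. It turned to lower for cell cycle genes (7.19e-05 in WT, 0.000588 in K700E) and for nonsense-mediated decay in WT (0.00738). For the difference of the effect it gave 0.851 for ribosomal proteins.

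Leaving out 1 sample at a time kept 408 values and changed 48 of the counts and lists, each named with its value in the report. The ranges were 0 to 17 events and 0 to 5 genes for the difference of the effect, 55 to 416 higher and 49 to 267 lower genes for K700E against WT, and adjusted p 0.012 to 0.091 for immediate early and stress genes in WT and 0.024 to 0.309 for the spliceosome core in K700E (called events). In spliced reads the adjusted p ranged from 0.0147 to 0.0759 for apoptosis regulators, 0.00737 to 0.156 for the spliceosome core and 0.0147 to 0.198 for DNA damage response in K700E against WT, and from 5.03e-14 to 0.936 for ribosomal proteins in the difference of the effect. The total event counts of the other contrasts kept within 1.5 times, at 330 to 370 for K700E against WT, 33966 to 35368 for H3B-8800 in WT and 33142 to 35062 in K700E, but the exons included less in K700E against WT ranged from 10 to 25, with 29 as reported. For the single events and genes named, 2805 values kept their call and 267 lost it.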

Other observations

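All events in this part were chosen after their values were seen, and no explanation for them was tested. Of the 194 alternative 3' sites raised in K700E, 39 rose further and 20 fell under H3B-8800 in K700E. Sites were chosen with the same K700E DMSO samples that H3B-8800 is compared with here, so falls are partly favoured by the choice. The TTI1 site, in a gene of a cochaperone of large checkpoint kinases (chromosome 20, 38002628 to 38002793), fell from 62.7% ± 5.18 to 19.5% ± 6.14 (n = 3, limma adjusted p = 0.000418), and the VPS9D1-AS1 site from 70.4% ± 1.71 to 49.6% ± 5.43 (adjusted p = 0.0205). Of the exons raised in K700E, that of BRD9 fell from 46.7% ± 4.54 to 13.1% ± 2.63 (adjusted p = 1.24e-05), that of TTC3 from 56.6% ± 2.82 to 24.98% ± 0.06 (adjusted p = 0.00345) and that of NOL9 from 39.2% ± 4.42 to 16.7% ± 1.53 (adjusted p = 0.00895). In WT these 5 events stood under 7% in both treatments. The test of the difference between genotypes did not call them (adjusted p = 0.307 for TTI1, 0.659 for VPS9D1-AS1, 0.19 for BRD9, 0.48 for TTC3 and 0.771 for NOL9).

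In DMSO the alternative 3' site of BCL2L1, a gene of the BCL2 family, was used at 39.4% ± 3.85 in WT and 75.6% ± 2.05 in K700E (difference 36.3 points, adjusted p = 0.0104), and H3B-8800 moved it the same way in both genotypes, with no detected difference of that effect (-23.5 points, adjusted p = 0.973). SF3B1 itself had a 3' site used at 0% in WT (up to 0.0509% by counting error) and 3.87% ± 0.44 in K700E in DMSO (adjusted p = 1.93e-07, under the size threshold). The exon form with that site (chromosome 2, 197402949 to 197403059) overlaps coding sequence but matches no annotated exon. Spliced reads of SF3B1 stood at 1006 to 1070 RPM in WT and 1004 to 1155 in K700E in DMSO, and at 1724 to 1836 and 1603 to 1784 in H3B-8800. Its intron on chromosome 2, 197418589 to 197420427, went from 8.96% to 2.73% in WT (adjusted p = 1.26e-05, under the size threshold), a fall where most called introns rose.

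Summed spliced reads of the T and NK cell markers were 95.5 to 217 RPM and of the myeloid markers 2.12 to 7.04 RPM in the 12 samples, against 6701 to 12206 for the B cell markers.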
